A study of Homo sapiens with 12 samples.

How the data were processed

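Total RNA was measured by sequencing in HCT116 cells, a human colorectal carcinoma line, in 12 libraries that fall into 4 groups of 3. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, ribosomal RNA was depleted and the libraries were made with a stranded total RNA kit. The replicates were dishes treated separately on a single day and are described as technical, so the p-values measure only the spread between these dishes.

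The deposited values were estimated counts per gene that need not be whole, as the authors' quantifier gave them. Over all libraries 76.1% of the values were whole numbers. The submitters' processing notes name STAR, RSEM 1.3.3, HTSeq 2.0.2, SAMtools 1.6, FastQC 0.12.0, Trim Galore 0.6.10 and DESeq2 1.44.0, with the human builds GRCh38 and hg38. The same notes name Bowtie2 2.5.4, Picard 2.21.4, bedtools 2.30.0, MACS2 2.2.9.1 and deepTools 3.1.1, and they tie no tool to a step. The annotation release and the strand setting of the counting are not given in the sources used here. Estimated counts divide reads shared by similar genes, so values of histone genes, small nuclear RNAs, ribosomal protein genes and other close copies are uncertain. Without a stated strand setting, antisense genes and overlapping genes are uncertain too.

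The table held 63241 Ensembl genes, and 49388 of them had at least 1 count in some library. A symbol was found for 42338 genes. Gene classes, spans and coordinates came from GENCODE 29 on GRCh38, which held 58228 of the identifiers. A class for another 393 genes came from a RefSeq gene table, matched by symbol, and 4620 genes were left with no class. Estimated counts were rounded to whole numbers before testing.

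Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 23593, and libraries were scaled by TMM. All 12 libraries entered a single quasi-likelihood fit with a mean for each group, robust moderation and 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Each treatment was compared with the controls, and the treatments were compared with each other, which gave 6 comparisons. Levels are given as CPM, counts scaled by TMM to a common library total, as mean ± SD over 3 libraries, and fold changes carry the standard error (SE) of the fit.

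Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01. The same test was repeated with the correlation estimated from the data. Adjustment ran over all 30 lists, 7 gene classes and 6 comparisons together. Beside each count over all genes tested, the report gives the count with p-values adjusted over the list alone. Classes with fewer than 10 tested genes were not tested, which left out microRNAs. With the preset correlation 84 of 180 list tests passed, and 4 of those 84 also passed with the estimated correlation. Of the 18 class tests that passed, 1 also did so with the estimated correlation. Those 5 were the p53 list with POLR1A depleted, the Pol III factors with POLR2A depleted, the KRAB zinc finger list with actinomycin D, the p53 list between actinomycin D and POLR1A depletion, and the protein-coding class between actinomycin D and POLR2A depletion.

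The lists, the tests of the comparisons, most alternatives and the rule for named genes were fixed before the data were examined, while most tests of explanations were chosen later. The rule names POLR1A and POLR2A in every library. In each comparison with the controls it names the 6 highest and the 6 lowest protein-coding genes by log2 fold change, and the 3 highest and 3 lowest non-coding genes with a symbol. Such genes had to pass the threshold, have an average log2 CPM of 3 or more and have every treated library on the same side of every control library. Each list adds up to 3 members with the largest changes among those that passed. Between treatments the rule takes the 5 highest and the 5 lowest protein-coding genes. Only part of the genes that the rule gives is named in the report.

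Where a group held no counts of a gene, the fold was bounded with a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio was given with an exact binomial 95% interval. These intervals and floors cover counting error only, and reads without molecular identifiers are not independent molecules.

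The edgeR step was tested on simulated data with 200 changed genes among 23593. In the simulated POLR1A comparison it recovered 52.2% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 87.9% of those changed 4-fold. Of 143 calls there, 7 were unchanged genes. The same shares were 56.7%, 76.1% and 90.9% for the POLR2A comparison, with 4 unchanged genes among 153 calls. For actinomycin D they were 58.2%, 80.6% and 97.0%, with 9 unchanged genes among 166 calls. Because 3 comparisons share the control libraries, 20 simulations set unchanged groups against those controls. They gave the covariance that sharing alone produces, and the overlap of calls among groups without changed genes.

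Library totals ran from 11289094 to 27393969 counts. Correlations of log2 CPM within groups ran from 0.970 to 0.984. The chi-square statistic between replicates of a group ran from 3.49 to 9.37 per degree of freedom, above sampling noise for every pair, so no library was counted as a repeat of another.

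Alternatives covered DESeq2 size factors, library totals alone, scaling to the 13 mitochondrially encoded mRNAs, no filter on low counts, the Wald test of DESeq2 1.42.0, a fit over only the groups compared, the replicate number as a block, an added limit of 1 on the absolute log2 fold change, and leaving out each library. A restriction to genes with an average log2 CPM of 3 or more was planned for gene length and was added for the other results after seeing the data. A coefficient planned for gene length is not reported here. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.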

Results

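Total RNA was profiled in HCT116 cells after loss of the largest subunit of RNA polymerase I or II, or after treatment with actinomycin D, a DNA-binding inhibitor of transcription. The study's design text asks how transcription by the 2 polymerases relates to genome organization, and which coding and non-coding transcripts change. The control group was wild-type HCT116 with DMSO. In the POLR1A line, endogenous POLR1A carried an auxin-inducible degron, a tag that leads to destruction of the protein once a ligand is added. These cells had doxycycline at 1 µg/ml from 24 h before the ligand, to induce the plant receptor OsTIR1, and then 500 µM indole-3-acetic acid. The POLR2A line carried a second-generation degron and had 5-Ph-IAA, a modified auxin, at 1 µM. Wild-type cells had actinomycin D at 5 µg/mL. Titles give 8 h for the control and degron groups and 6 h for actinomycin D, while the extraction text gives harvest at 6 h. Neither degron line had untreated libraries of its own here, so line, inducer and ligand go together with each depletion.

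Totals ran from 12235068 to 17535685 counts in the controls, 18796962 to 21802217 with POLR1A depleted, 11289094 to 15037410 with POLR2A depleted and 20302164 to 27393969 with actinomycin D. Genes with at least 1 count numbered 38236 ± 914 in the POLR2A-depleted libraries, against 31138 ± 527 in the controls, 32686 ± 421 with POLR1A depleted and 30862 ± 874 with actinomycin D (SD, n = 3 each). Mitochondrially encoded RNA made up 7.30% ± 1.08 of control counts, 5.79% ± 0.21 with POLR1A depleted, 9.60% ± 0.87 with POLR2A depleted and 3.56% ± 0.08 with actinomycin D (SD, n = 3 each).

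The degron removes protein, so mRNA levels of the targeted genes do not check the labels. POLR1A (ENSG00000068654), which encodes the largest Pol I subunit, stood at 230 to 249 CPM in the control libraries and 145 to 151 CPM in the POLR1A-depleted ones. Its range was 128 to 142 CPM with POLR2A depleted and 177 to 203 CPM with actinomycin D. POLR2A (ENSG00000181222), which encodes the largest Pol II subunit, stood at 468 to 561 CPM in controls, 908 to 945 CPM with POLR1A depleted, 1070 to 1110 CPM with POLR2A depleted and 558 to 620 CPM with actinomycin D. Against controls, POLR1A mRNA fell by 0.69, 0.82 and 0.32 on the log2 scale in the POLR1A-depleted, POLR2A-depleted and actinomycin D libraries. POLR2A mRNA rose by 0.84, 1.09 and 0.19 (SE 0.06 for each of these changes). The POLR1A change with actinomycin D turned to 0.59 when libraries were scaled to mitochondrial mRNAs, and the POLR2A change there lost its call without actinomycin D replicate 2, at 0.15.

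**Figure D1:**
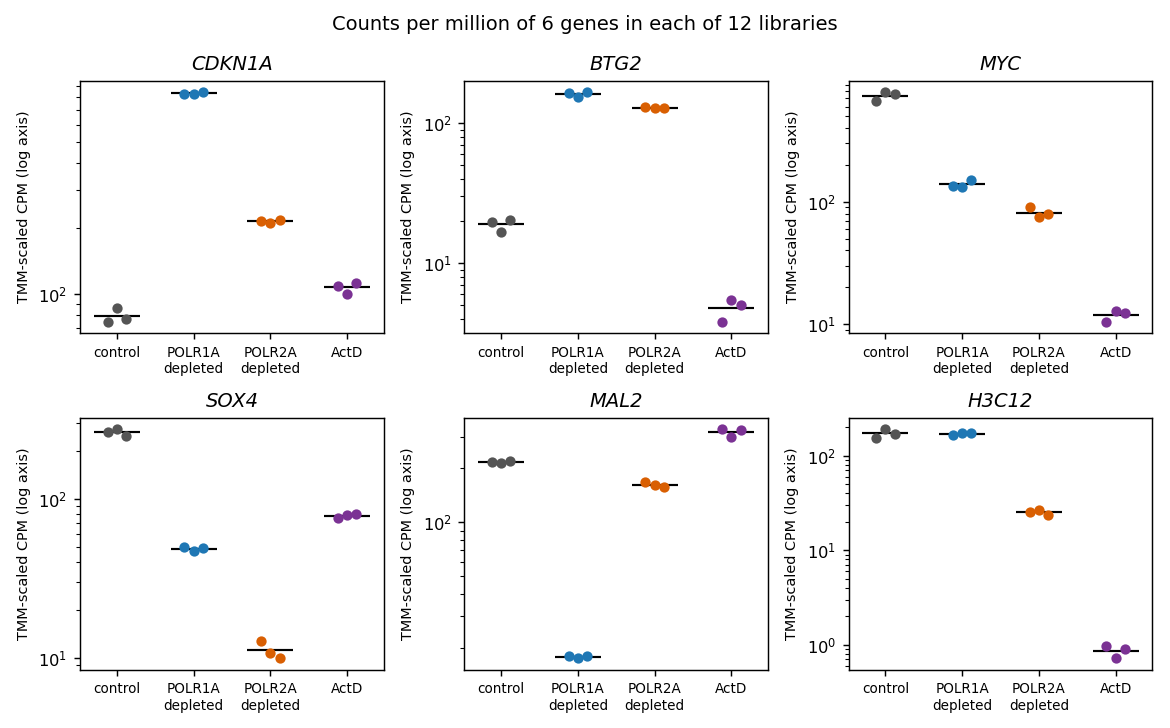
TMM-scaled CPM (log axis) of 6 genes in each of the 12 libraries by group, with points for libraries and lines for group means. CDKN1A lay at 835 CPM on average with POLR1A depleted and 79.5 in controls, MAL2 at 17.9 and 217, MYC at 11.9 with actinomycin D and 735 in controls, H3C12 at 0.86 and 172, and SOX4 at 11.1 with POLR2A depleted and 261 in controls.

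With POLR1A depleted, genes of the p53 response were among the highest, and GALNT3 and MAL2 were among the lowest with an average log2 CPM of 3 or more. CDKN1A (chr6:36676460-36687339), which encodes the cell-cycle inhibitor p21, rose 10.5-fold to 835 ± 6.81 CPM from 79.5 ± 6.3 in controls (SD, n = 3 each). BTG2, an antiproliferative gene, rose 8.53-fold, SESN1, a stress-induced sestrin, 7.81-fold, and FAS, a death receptor, 6.67-fold. GALNT3 (chr2:165747591-165794682), a transferase that starts mucin-type glycosylation, fell by 4.63 on the log2 scale (SE 0.21), from 16.6 ± 0.717 to 0.669 ± 0.331 CPM. MAL2 (chr8:119165034-119245673), a protein of apical transport in epithelia, fell from 217 ± 3.84 to 17.9 ± 0.343 CPM (SD, n = 3 each).

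The comparison called 4851 genes higher and 4380 lower of 23593 tested, and 1165 and 1156 of these had an absolute log2 fold change of 1 or more. Of the calls 52.6% were higher. Scaling to mitochondrial mRNAs moved that share to 85.1% and the median of all genes from 0.013 to 0.369, so small falls depend on the scaling.

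Of the 30 p53 target genes 28 rose and 0 fell, and adjusted over the list alone the counts were the same 28 and 0. Their median log2 fold change was 1.64, with a middle range from 0.93 to 2.19 (camera adjusted p = 1.33e-26, and adjusted p = 0.0104 with an estimated correlation). Other named genes that rose were NRP1 (chr10:33177492-33336262), a semaphorin and VEGF co-receptor, by 3.32 (SE 0.16), and INKA2 (chr1:111680630-111739424), an inhibitor of the kinase PAK4, by 3.17 (SE 0.19). MIR34AHG, the host transcript of the p53-induced microRNA miR-34a, rose by 2.51 (SE 0.14), LUCAT1 by 1.59 (SE 0.17) and MIR181A1HG by 1.36 (SE 0.15).

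Genes for making ribosomes fell together. Of 40 ribosome biogenesis factors 39 fell and 0 rose, 39 and 0 adjusted over the list alone, with a median of -0.77 (camera adjusted p = 8.04e-26, adjusted p = 0.125 with an estimated correlation). RRP9, a component of the U3 particle that processes ribosomal RNA, fell by 1.34 (SE 0.06), NOP16 by 1.31 (SE 0.11) and RRS1 by 1.3 (SE 0.12). Of 15 Pol I subunits and initiation factors 12 fell and 1 rose, 12 and 2 adjusted over the list alone, with a median of -0.63 (adjusted p = 1.52e-05, adjusted p = 0.125 with an estimated correlation). POLR1G fell by 1.89 (SE 0.09), POLR1E by 0.95 (SE 0.07) and POLR1B by 0.92 (SE 0.06). Of 21 host genes of small nucleolar RNAs 18 fell and 0 rose, both overall and adjusted over the list alone, with a median of -0.73 (adjusted p = 4.05e-11, adjusted p = 0.0628 with an estimated correlation). EPB41L4A-AS1 fell by 1.82 (SE 0.10) and SNHG15 by 1.47 (SE 0.10).

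Ribosomal protein mRNAs had smaller changes. Of 79 such genes 54 fell and 0 rose, 63 and 0 adjusted over the list alone, with a median of -0.33, which became 0.03 under scaling to mitochondrial mRNAs (adjusted p = 5.61e-13, adjusted p = 0.453 with an estimated correlation). RPS26 fell by 0.77 (SE 0.16) and RPL10A by 0.69 (SE 0.06). The rRNA list held MT-RNR1, MT-RNR2 and 3 copies of the 5.8S gene with identical shared reads. Of its 5 members 4 fell, also adjusted over the list alone, with a median of -1.26, in libraries from which rRNA had been depleted (adjusted p = 0.0299, adjusted p = 0.501 with an estimated correlation).

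Genes of replication and of sterol synthesis fell. Of 25 genes of G1/S and replication 21 fell and 1 rose, the same adjusted over the list alone, with a median of -0.78 (adjusted p = 9.19e-15, adjusted p = 0.127 with an estimated correlation). E2F2, a transcription factor of S-phase entry, fell by 1.94 (SE 0.09), the licensing factor CDT1 by 1.49 (SE 0.06) and MCM10 by 1.3 (SE 0.06). Of 20 genes of the cholesterol and sterol response 17 fell and 2 rose, the same adjusted over the list alone, with a median of -0.41 (adjusted p = 7.46e-07, adjusted p = 0.238 with an estimated correlation). INSIG1, a sensor that restrains sterol synthesis, fell by 2.02 (SE 0.11) and the synthesis enzyme SQLE by 1.5 (SE 0.07).

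Members of the ATF4 list moved in both directions. Of 25 genes of the ATF4 and unfolded protein response 13 fell and 6 rose, 14 and 6 adjusted over the list alone (median -0.47, adjusted p = 0.0143, adjusted p = 0.372 with an estimated correlation). DDIT4, an mTOR inhibitor, fell by 1.23 (SE 0.12), while SESN2, also in the p53 list, rose by 2.60 (SE 0.10) and the cystine transporter SLC7A11 by 1.71 (SE 0.05). Of 15 NF-kB and inflammatory targets 8 fell and 0 rose, the same adjusted over the list alone (median -0.61, -0.44 with genes at the floor set to their bound, adjusted p = 0.0119, adjusted p = 0.127 with an estimated correlation), among them the apoptosis inhibitor BIRC3, which fell by 2.03 (SE 0.14). MYC, the growth transcription factor, fell by 2.40 (SE 0.08), while EGR2 and EGR3, factors induced by growth signals, rose by 2.23 (SE 0.21) and 2.07 (SE 0.12). These 3 belong to the immediate early list, of which 13 of 30 rose and 7 fell, 15 and 7 adjusted over the list alone, without a call for the list (adjusted p = 0.107).

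Markers of intestinal epithelium moved in the same libraries. Of 12 tested markers 8 fell and 2 rose, the same adjusted over the list alone, with a median of -0.62 (adjusted p = 0.000317, adjusted p = 0.125 with an estimated correlation). CDH1, the epithelial cadherin, fell by 1.79 (SE 0.07). Other genes at the low end were VSNL1, a calcium sensor, which fell by 3.59 (SE 0.17), the kinase SYK, which fell by 3.30 (SE 0.20), and the calcium-binding protein S100A14, which fell by 2.99 (SE 0.10). PPP1R12C (chr19:55090913-55117559), a regulatory subunit of myosin phosphatase, fell by 3.64 (SE 0.11), from 41.5 ± 3.71 to 3.32 ± 0.225 CPM (SD, n = 3 each). Among non-coding genes MIR663AHG fell by 3.49 (SE 0.45), LINC00861 fell by 2.46 (SE 0.18) and LINC02964 by 2.29 (SE 0.17). Of 31 KRAB zinc finger genes 17 fell and 3 rose, 17 and 4 adjusted over the list alone, with a median of -0.34 that became 0.02 under scaling to mitochondrial mRNAs (adjusted p = 0.00325, adjusted p = 0.149 with an estimated correlation). ZNF595, a weakly expressed member, had 3 counts over the POLR1A-depleted libraries and 246 over controls, a ratio of 0.00897 with a counting interval from 0.00184 to 0.0265.

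Other lists had no call with POLR1A depleted, where counts are given as higher and lower members. Of 40 histone genes 8 and 11 passed, 8 and 12 adjusted over the list alone (median -0.19, 0.17 under scaling to mitochondrial mRNAs, mean 0.2, adjusted p = 0.15). Of 21 Pol III subunits and factors 4 and 9 passed, 5 and 10 adjusted over the list alone (adjusted p = 0.0557), and of 18 Pol II subunits 5 and 5 in both ways (adjusted p = 0.608). Short-lived mRNAs had 11 and 12 of 31, 13 and 15 adjusted over the list alone (adjusted p = 0.543), and long-lived mRNAs 5 and 11 of 30 in both ways (adjusted p = 0.265). Heat shock genes had 8 and 3 of 16, 8 and 4 adjusted over the list alone (adjusted p = 0.222), and G2/M genes 9 and 4 of 25, 9 and 6 adjusted over the list alone (adjusted p = 0.521). Genes of chromatin architecture had 10 and 8 of 30, 10 and 11 adjusted over the list alone (median -0.07, 0.29 under scaling to mitochondrial mRNAs, mean 0.01, adjusted p = 0.849). Interferon genes had 5 and 3 of 21, mesenchymal markers 6 and 4 of 13, blood cell markers 0 and 1 of 11 and neural markers 1 and 1 of 9, all the same adjusted over the list alone (adjusted p = 0.61, 0.342, 0.657 and 0.657).

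With POLR2A depleted, SOX4 and PRKAA2 were among the lowest genes, and many weakly expressed genes were higher than in controls. SOX4 (chr6:21592768-21598619), a developmental transcription factor, fell by 4.54 on the log2 scale (SE 0.08), from an average of 261 to 11.1 CPM, and MYC fell by 3.17 (SE 0.09), from 735 ± 64.2 to 81.6 ± 7.9 CPM (SD, n = 3 each). PRKAA2 (chr1:56645322-56715335), a catalytic subunit of the energy sensor AMPK, had 3 counts over the POLR2A-depleted libraries and 486 over controls, a ratio of 0.00656 with a counting interval from 0.00135 to 0.0193, or 0.00356 without POLR2A-depleted replicate 2. APOLD1 (chr12:12725917-12829975), an endothelial early response gene, rose 36.3-fold to 30.8 ± 2.08 CPM from 0.87 ± 0.329 (SD, n = 3 each).

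The comparison called 7830 genes higher and 6645 lower, and 5181 and 2274 of these had an absolute log2 fold change of 1 or more. Higher genes were 54.1% of the calls, 38.6% under scaling to mitochondrial mRNAs, and 31.7% among genes with an average log2 CPM of 3 or more. The median of all genes was 0.084, -0.203 under scaling to mitochondrial mRNAs and 0.208 with library totals alone.

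The direction depended on abundance. Tested genes were put into 5 equal groups by average log2 CPM. In the lowest group 2332 genes rose and 159 fell, with a median of 1.6. In the top group 1081 rose and 2507 fell, with a median of -0.20. The POLR2A-depleted libraries entered both the filter and the average, so genes that rose there could enter the lowest group because they rose. With the 18557 genes that passed by the POLR1A-depleted and actinomycin D libraries alone, ordered by these, a choice made after the values were seen, 1058 rose and 306 fell in the lowest group, with a median of 0.39, and 880 rose and 1921 fell in the top group, with a median of -0.17. The lowest and top groups by the average over all libraries had medians of 0.00 and 0.03 with POLR1A depleted, and of -0.38 and 0.22 with actinomycin D.

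**Figure D2:**
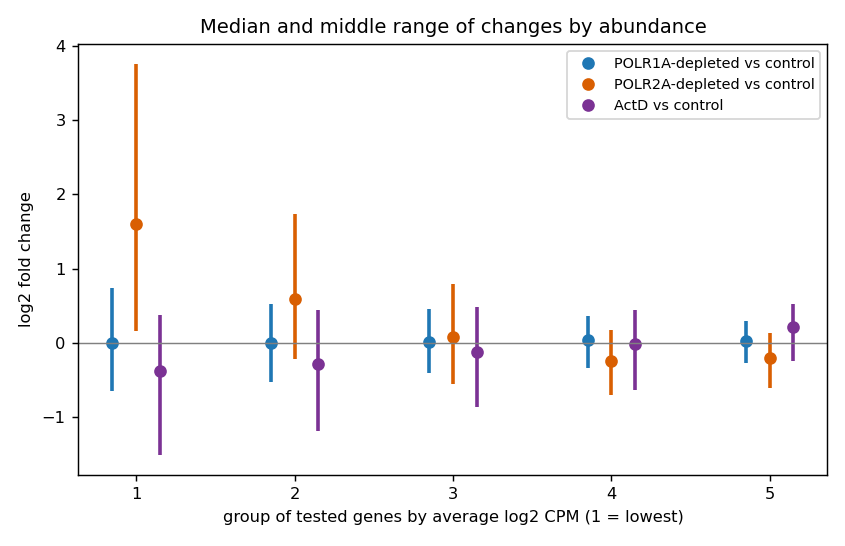
Log2 fold change against controls (vertical axis) in 5 equal groups of tested genes ordered by average log2 CPM (horizontal axis), with points for medians and lines for the middle range of genes. With POLR2A depleted the median went from 1.6 in the lowest group (0.39 with genes passing and ordered by the other treatments) to -0.20 in the highest, and with POLR1A depleted it stayed between 0.00 and 0.04.

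Among the lowest genes with an average log2 CPM of 3 or more, GLI2, a Hedgehog transcription factor, fell by 3.95 (SE 0.21), the axon guidance ligand SEMA3A by 3.74 (SE 0.09), the homeobox gene MKX by 3.74 (SE 0.10) and the ubiquitin ligase MID1 by 3.55 (SE 0.06). Of 31 short-lived mRNAs 22 fell and 4 rose, the same adjusted over the list alone, with a median of -0.63 (adjusted p = 1.35e-05, adjusted p = 0.29 with an estimated correlation). Of 30 immediate early genes 17 fell and 6 rose, the same adjusted over the list alone, with a median of -0.42 (adjusted p = 0.00779, adjusted p = 0.569 with an estimated correlation). ATF3, a stress-induced factor in both lists, rose by 2.21 (SE 0.10).

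Genes of chromatin architecture, of Pol I and Pol III and of ribosome production fell. Of 30 genes of chromatin architecture and heterochromatin 23 fell and 3 rose, 24 and 3 adjusted over the list alone, with a median of -0.56 (adjusted p = 1.66e-06, adjusted p = 0.14 with an estimated correlation). CTCF, the insulator protein, fell by 2.01 (SE 0.08), the H3K9 methyltransferase SETDB1 by 1.62 (SE 0.08) and the cohesin release factor WAPL by 1.39 (SE 0.06). Of 21 Pol III subunits and factors 17 fell and 2 rose, the same adjusted over the list alone, with a median of -0.67 (adjusted p = 2.45e-06, adjusted p = 0.0363 with an estimated correlation), and POLR3E and POLR3B fell by 2.07 (SE 0.07) and 1.96 (SE 0.09). Of 15 Pol I subunits and initiation factors 12 fell and 0 rose, 13 and 0 adjusted over the list alone, with a median of -0.60 (adjusted p = 2.02e-05, adjusted p = 0.125 with an estimated correlation). Of 40 ribosome biogenesis factors 37 fell and 0 rose, the same adjusted over the list alone, with a median of -0.69 (adjusted p = 9.19e-15, adjusted p = 0.189 with an estimated correlation), and WDR43 fell by 1.83 (SE 0.06). Of 21 host genes of small nucleolar RNAs 17 fell and 1 rose, the same adjusted over the list alone, with a median of -1.18 (adjusted p = 3.47e-08, adjusted p = 0.0875 with an estimated correlation), and SNHG1 fell by 2.37 (SE 0.05).

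Cell-cycle, sterol, stress and histone lists also fell with POLR2A depleted. Of 25 G2/M genes 19 fell and 2 rose, the same adjusted over the list alone (median -0.48, adjusted p = 3.06e-06, adjusted p = 0.282 with an estimated correlation), with the spindle checkpoint kinases BUB1B and TTK falling by 1.5 (SE 0.06) and 1.37 (SE 0.08). Of 25 genes of G1/S and replication 15 fell and 4 rose, the same adjusted over the list alone (median -0.25, adjusted p = 0.0135, adjusted p = 0.591 with an estimated correlation). Of 20 sterol genes 16 fell and 1 rose, the same adjusted over the list alone (median -0.67, adjusted p = 3.47e-06, adjusted p = 0.275 with an estimated correlation), and SQLE fell by 2.5 (SE 0.07). Among 25 genes of the ATF4 and unfolded protein response 19 fell and 5 rose, the same adjusted over the list alone (median -0.65, adjusted p = 0.000225, adjusted p = 0.222 with an estimated correlation), and ATF4 itself fell by 2.03 (SE 0.06). Of 31 KRAB zinc finger genes 22 fell and 4 rose, the same adjusted over the list alone (median -0.76, adjusted p = 0.000132, adjusted p = 0.112 with an estimated correlation). Of 40 replication-dependent histone genes 34 fell and 5 rose, the same adjusted over the list alone (median -1.6, adjusted p = 3.05e-13, adjusted p = 0.236 with an estimated correlation), and H3C4 fell by 3.1 (SE 0.29).

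Other lists were higher with POLR2A depleted. Of 30 p53 target genes 24 rose and 2 fell, the same adjusted over the list alone, with a median of 0.75 (adjusted p = 4.89e-08, adjusted p = 0.0703 with an estimated correlation). BTG2 rose by 2.77 (SE 0.08) and FAS by 2.53 (SE 0.08). Of 21 interferon response genes 14 rose and 1 fell, the same adjusted over the list alone, with a median of 0.79 (adjusted p = 0.0084, adjusted p = 0.125 with an estimated correlation). Among its 8 members with an average log2 CPM of 3 or more, a limit chosen after the values were seen, 5 rose and 1 fell, with a median of 0.30. OAS2, an antiviral enzyme, rose by 5.34 (SE 0.46), from 0.164 ± 0.0814 to 7.17 ± 0.614 CPM (SD, n = 3 each). NEAT1, the architectural RNA of paraspeckles, rose by 1.87 (SE 0.19).

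Some markers of other cell types rose in these libraries. Of 11 blood cell markers 7 rose and 1 fell, the same adjusted over the list alone, without a call for the list (median 2.34, adjusted p = 0.0832). The monocyte receptor CD14 had 0 control counts and was at least 59.3-fold higher, or 38.1 and 37.5 without control replicate 2 or 3, and the integrin ITGAM rose by 4.91 (SE 0.42), to 9.79 ± 2.44 CPM, or by 5.77 without control replicate 3. LGR5, a stem-cell marker of the intestine, had 0 control counts and was at least 320-fold higher, at 20.6 ± 1.53 CPM, or 205 and 202 without control replicate 2 or 3. Of 9 neural markers 2 rose and 2 fell, and of 13 mesenchymal markers 7 rose and 3 fell, 7 and 4 adjusted over the list alone, without a call for either list (adjusted p = 0.657 and 0.476). Protein-coding genes at the high end were LVRN, an aminopeptidase, up by 4.58 (SE 0.22), the neural adhesion gene CNTN2 by 4.29 (SE 0.18), TNXB by 4.13 (SE 0.19), TEX14 by 4.01 (SE 0.22) and the carboxypeptidase gene CPM by 3.98 (SE 0.14). TNXB has a partial copy nearby, so its value is uncertain. The non-coding genes ST3GAL6-AS1 and MIR31HG rose by 4.83 (SE 0.18) and 3.38 (SE 0.18), and PHLDA1-AS1 fell by 6.59 (SE 0.40), or 7.60 without POLR2A-depleted replicate 2.

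Lists without a call with POLR2A depleted included the ribosomal proteins, of which 12 were higher and 10 lower of 79, 9 and 5 adjusted over the list alone (adjusted p = 0.837). Long-lived mRNAs had 15 higher and 4 lower of 30, 16 and 4 adjusted over the list alone (adjusted p = 0.0559), and Pol II subunits 8 and 4 of 18 in both ways (adjusted p = 0.64). NF-kB targets had 4 higher and 9 lower of 15, intestinal markers 3 and 7 of 12 and heat shock genes 4 and 6 of 16, the same adjusted over the list alone (adjusted p = 0.21, 0.185 and 0.444). Of 14 aryl hydrocarbon receptor targets 4 were higher and 7 lower, 6 and 7 adjusted over the list alone (adjusted p = 0.473). In the NF-kB, intestinal and receptor target lists the medians of -0.35, -0.39 and -0.12 and the tests pointed down, while the means were 0.13, 0.88 and 0.52. None of the 5 rRNA genes passed (adjusted p = 0.329).

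With actinomycin D, replication-dependent histone mRNAs and unstable mRNAs fell furthest, and mRNAs with long lives made up more of the libraries. H2AC7 (chr6:26198851-26199243) had 0 counts in the actinomycin D libraries and was at least 2970-fold lower than the 137 ± 30.3 CPM in controls, or 1820-fold without actinomycin D replicate 2, the deepest. H3C12 (chr6:27890382-27893106) fell by 7.66 on the log2 scale (SE 0.12), from 172 ± 18.4 to 0.86 ± 0.13 CPM, and MYC fell by 5.94 (SE 0.10), from 735 ± 64.2 to 11.9 ± 1.23 CPM (SD, n = 3 each). SESN3 (chr11:95165513-95232541), a stress-response sestrin, rose 4.23-fold to 24.4 ± 0.324 CPM from 5.72 ± 0.734 (SD, n = 3 each).

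The comparison called 5879 genes higher and 6722 lower, and 916 and 4008 of these had an absolute log2 fold change of 1 or more. Higher genes were 46.7% of the calls and 85.2% under scaling to mitochondrial mRNAs, which themselves fell with this drug. The median of all genes was -0.061, 0.823 under that scaling and -0.177 with library totals alone.

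Of 40 replication-dependent histone genes 36 fell and 0 rose, the same adjusted over the list alone, with a median of -5.95, the same with genes at the floor set to their bound (adjusted p = 2.39e-18, adjusted p = 0.176 with an estimated correlation). H3C4 fell by 9.01 (SE 0.50), H2BC11 fell by 7.47 (SE 0.17) and H2AC11 fell by 7.43 (SE 0.11). H4C12 fell by 8.18 (SE 0.50), but all of its 73 counts lay in actinomycin D replicate 2, without which it was at least 4300-fold lower. Of 31 short-lived mRNAs 30 fell and 0 rose, the same adjusted over the list alone, with a median of -2.69 (adjusted p = 1.67e-19, adjusted p = 0.0776 with an estimated correlation). Of 30 immediate early genes 29 fell and 1 rose, the same adjusted over the list alone, with a median of -2.70 (adjusted p = 1.28e-15, adjusted p = 0.125 with an estimated correlation). The phosphatase DUSP5 fell by 4.18 (SE 0.10), the matrix protein CCN1 by 4.07 (SE 0.11) and SERTAD1 fell by 4.21 (SE 0.15). Of 15 NF-kB and inflammatory targets 9 fell and 0 rose, 10 and 0 adjusted over the list alone, with a median of -1.84, or -1.6 with genes at the floor set to their bound (adjusted p = 0.000317, adjusted p = 0.0703 with an estimated correlation), and NFKBIA, the inhibitor of NF-kB, fell by 4.11 (SE 0.12).

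All 31 KRAB zinc finger genes tested fell, also adjusted over the list alone, with a median of -1.66 (adjusted p = 3.73e-13, adjusted p = 0.024 with an estimated correlation). ZNF263 fell by 2.91 (SE 0.11), ZNF267 by 2.49 (SE 0.10) and ZNF317 fell by 2.46 (SE 0.07). Of 30 p53 target genes 12 rose and 14 fell, the same adjusted over the list alone, without a call for the list (median -0.07, 0.85 under scaling to mitochondrial mRNAs, adjusted p = 0.694). The kinase gene PLK2 fell by 4.02 (SE 0.09) and the nuclease gene AEN by 2.28 (SE 0.08). Among 25 genes of the ATF4 and unfolded protein response 9 rose and 13 fell, the same adjusted over the list alone, without a call (adjusted p = 0.471), and DDIT4 fell by 4.88 (SE 0.16), TRIB3 by 3.76 (SE 0.12) and XBP1 by 3.54 (SE 0.09). Of 16 heat shock genes 8 rose and 6 fell, the same adjusted over the list alone, without a call (median 0.19, mean -0.22, adjusted p = 0.561), and DNAJB1 fell by 3.03 (SE 0.07).

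Ribosomal protein genes, long-lived mRNAs and Pol II subunits rose relative to the other RNAs in the libraries. Of 79 cytosolic ribosomal protein genes 73 rose and 1 fell, 74 and 1 adjusted over the list alone, with a median of 0.62 (adjusted p = 1.65e-20, adjusted p = 0.311 with an estimated correlation). RPS19 rose by 0.95 (SE 0.06), RPL39 by 0.94 (SE 0.09) and RPS12 by 0.92 (SE 0.08). Of 30 long-lived mRNAs 27 rose and 1 fell, the same adjusted over the list alone, with a median of 0.61 (adjusted p = 5.72e-13, adjusted p = 0.262 with an estimated correlation), and FTL, ferritin light chain, rose by 1.12 (SE 0.06). Of 18 Pol II subunits 15 rose and 1 fell, the same adjusted over the list alone, with a median of 0.44 (adjusted p = 0.000207, adjusted p = 0.303 with an estimated correlation), and POLR2L and POLR2E rose by 0.82 (SE 0.14) and 0.76 (SE 0.06). Other named genes that rose were the neurotrophin receptor NGFR, by 1.88 (SE 0.12), the retinal reductase DHRS3, by 1.6 (SE 0.11), the cytoskeletal adducin ADD3, by 1.58 (SE 0.06), and the tight junction gene TJP3, by 1.57 (SE 0.10).

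Lists without a call with actinomycin D included the cell-cycle and sterol genes, with the same counts adjusted over the list alone. Of 25 genes of G1/S and replication 13 rose and 8 fell (median 0.18, mean -0.06, adjusted p = 0.336), of 25 G2/M genes 9 and 9 (adjusted p = 0.64) and of 20 sterol genes 11 and 8 (median 0.24, mean -0.09, adjusted p = 0.649). Of 30 genes of chromatin architecture 15 rose and 13 fell, 15 and 14 adjusted over the list alone (median 0.08, -0.04 with library totals alone, mean -0.13, adjusted p = 0.656). Interferon genes had 6 rising and 4 falling of 21, receptor targets 5 and 6 of 14, intestinal markers 2 and 4 of 12 and mesenchymal markers 5 and 4 of 13, the same adjusted over the list alone (adjusted p = 0.595, 0.64, 0.307 and 0.909). The receptor targets had a median of 0.15, or -0.23 with genes at the floor set to their bound, and a mean of -0.09. Neural markers had 3 rising and 1 falling of 9, the same adjusted over the list alone, blood cell markers 0 and 1 of 11, 0 and 0 adjusted over the list alone, and none of the 5 rRNA genes passed (adjusted p = 0.417, 0.992 and 0.742).

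Factors for the other polymerases and for ribosome assembly fell relative to the median, with a sign that depended on the scaling. Of 15 Pol I subunits and initiation factors 12 fell and 0 rose, 13 and 0 adjusted over the list alone, with a median of -0.56 that became 0.37 under scaling to mitochondrial mRNAs (adjusted p = 2.61e-05, adjusted p = 0.125 with an estimated correlation). Of 21 Pol III subunits and factors 14 fell and 6 rose, the same adjusted over the list alone, with a median of -0.59 that became 0.33 (adjusted p = 0.0163, adjusted p = 0.149 with an estimated correlation). Of 40 ribosome biogenesis factors 23 fell and 6 rose, the same adjusted over the list alone, with a median of -0.31 that became 0.62 (adjusted p = 6.17e-05, adjusted p = 0.486 with an estimated correlation). Of 21 host genes of small nucleolar RNAs 15 fell and 3 rose, the same adjusted over the list alone, with a median of -0.93 (adjusted p = 1.85e-05, adjusted p = 0.128 with an estimated correlation).

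All 13 mitochondrially encoded mRNAs fell with actinomycin D, also adjusted over the list alone, by amounts that differed among them (median -1.63, adjusted p = 5.68e-06, adjusted p = 0.406 with an estimated correlation). MT-ND2 fell by 4.06 (SE 0.18), MT-ND1 fell by 3.94 (SE 0.18) and MT-ND5 by 2.26 (SE 0.16), all subunits of respiratory complex I. The mitochondrial tRNA gene MT-TI had 3 counts against 696 in controls, a ratio of 0.00309 with a counting interval from 0.000636 to 0.00908, or 0.00144 without actinomycin D replicate 1. With POLR1A depleted 4 of the 13 mRNAs fell, and with POLR2A depleted 2 rose, 3 and 2 adjusted over the list alone, without a call for the list in either (adjusted p = 0.0623 and 0.21). TALAM1, the antisense RNA of MALAT1, had 0 counts and was at least 514-fold lower with actinomycin D, or 315 without actinomycin D replicate 2 and 338 without control replicate 1, uncertain because of its overlap with MALAT1.

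**Figure D3:**
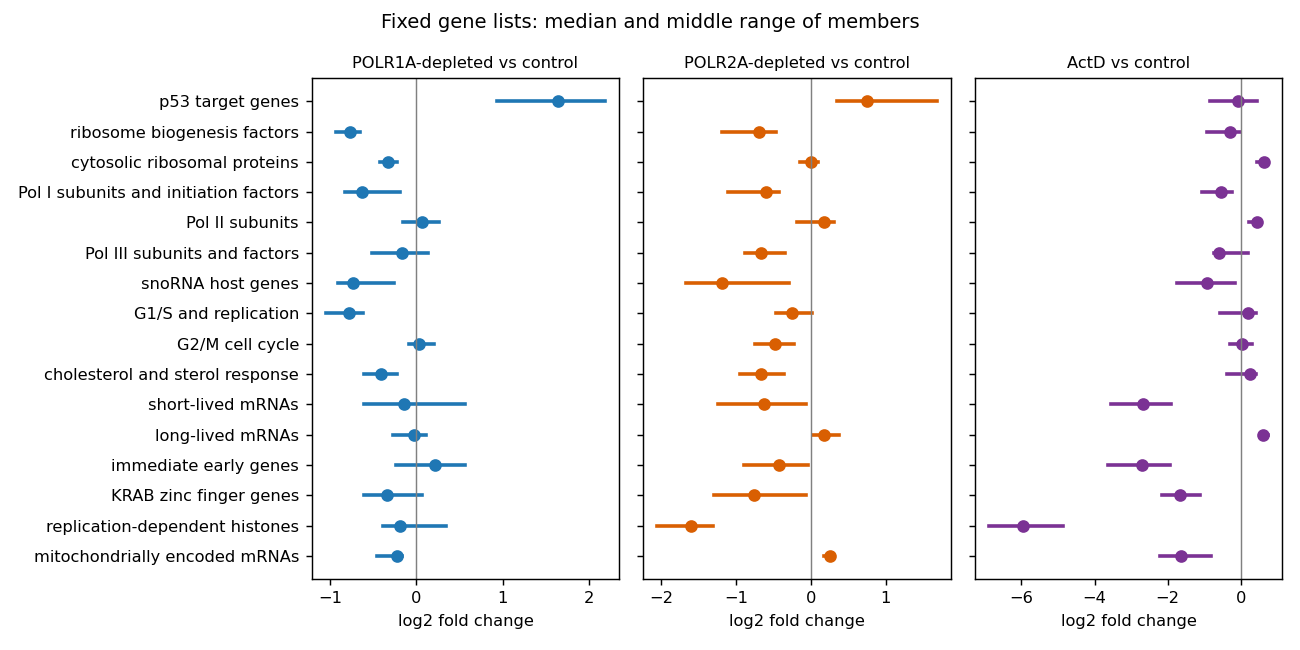
Median log2 fold change against controls (points, horizontal axis) and middle range of members (lines) for 16 fixed gene lists in the 3 treatments. The p53 list had medians of 1.64 with POLR1A depleted, 0.75 with POLR2A depleted and -0.07 with actinomycin D, and the histone list had -0.19, -1.6 and -5.95, where scaling to mitochondrial mRNAs turned the -0.07 to 0.85 and the -0.19 to 0.17.

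Coding and non-coding classes moved apart with POLR2A depleted and with actinomycin D. Of 4118 long non-coding RNAs tested, 1733 rose and 403 fell with POLR2A depleted, 1688 and 390 adjusted over the class alone (median 0.70, adjusted p = 2.45e-05, adjusted p = 0.178 with an estimated correlation). With actinomycin D 191 rose and 1169 fell, 148 and 1051 adjusted over the class alone (median -0.50, 0.36 under scaling to mitochondrial mRNAs, adjusted p = 0.00537, adjusted p = 0.33 with an estimated correlation). With POLR1A depleted 335 rose and 430 fell, 225 and 312 adjusted over the class alone, without a call for the class (adjusted p = 0.543). Of 14958 protein-coding genes 4798 rose and 5794 fell with POLR2A depleted, 4869 and 5856 adjusted over the class alone. The test pointed down (median -0.05, 0.07 with library totals alone, mean 0.33, adjusted p = 1.99e-05, adjusted p = 0.076 with an estimated correlation). With actinomycin D 5292 rose and 4496 fell, 5380 and 4585 adjusted over the class alone. The test pointed up (median 0.06, -0.04 with library totals alone, mean -0.14, adjusted p = 0.0157, adjusted p = 0.203 with an estimated correlation). Of 41 small nuclear RNAs 15 fell and 0 rose with POLR1A depleted, the same adjusted over the class alone (median -1.15, adjusted p = 0.000565, adjusted p = 0.439 with an estimated correlation). With POLR2A depleted 23 of them fell and 1 rose, 22 and 1 adjusted over the class alone (median -1.42, adjusted p = 0.0012, adjusted p = 0.461 with an estimated correlation). Of 71 small nucleolar RNAs 6, 17 and 8 fell and 0, 4 and 11 rose in the POLR1A, POLR2A and actinomycin D comparisons, with falls of 0, 9 and 8 and rises of 0, 3 and 11 adjusted over the class alone, without a call for the class (adjusted p = 0.0822, 0.0606 and 0.436). Of 1933 processed pseudogenes, which share reads with their parent genes, 418 rose and 162 fell with POLR2A depleted, 350 and 120 adjusted over the class alone, without a call (adjusted p = 0.273). Genes with no class rose with POLR2A depleted in 533 cases and fell in 122, 518 and 114 adjusted over the class alone (median 0.70, adjusted p = 0.000348, adjusted p = 0.203 with an estimated correlation). With actinomycin D 68 of them rose and 366 fell, 53 and 313 adjusted over the class alone (median -0.47, 0.35 under scaling to mitochondrial mRNAs, adjusted p = 0.0453, adjusted p = 0.453 with an estimated correlation). The pooled remaining classes had no call in the POLR1A, POLR2A and actinomycin D comparisons (adjusted p = 0.699, 0.0691 and 0.304).

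Between the depletions, PRKAA2, ZNF608 and GLI2 were higher with POLR1A depleted, and weakly expressed genes were higher with POLR2A depleted. PRKAA2 had 1050 counts with POLR1A depleted and 3 with POLR2A depleted, a ratio of 242 with a counting interval from 82.7 to 1180, or 447 without POLR2A-depleted replicate 2. ZNF608 was higher by 4.29 (SE 0.16), GLI2 by 3.79 (SE 0.21), ENOX1 by 3.27 (SE 0.18) and KLF12 by 3.19 (SE 0.11). CNTN2 was lower with POLR1A depleted, at a log2 fold change of -4.53 (SE 0.18), as were CFAP43, a gene of motile cilia, at -4.39 (SE 0.15), GALNT3 at -3.98 (SE 0.22), PPP1R12C at -3.68 (SE 0.11) and TEX14 at -3.45 (SE 0.20). In all 6855 genes were higher with POLR1A depleted and 7822 lower, 46.7% and 74.3% higher under scaling to mitochondrial mRNAs, which moved the median from -0.081 to 0.561. Among genes with an average log2 CPM of 3 or more 69.9% of calls were higher.

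Lists differed between the depletions too. Of 30 p53 target genes 25 were higher and 2 lower with POLR1A depleted than with POLR2A depleted, the same adjusted over the list alone (median 0.58, adjusted p = 1.83e-08, adjusted p = 0.0703 with an estimated correlation). Of 40 histone genes 35 were higher and 2 lower, the same adjusted over the list alone (median 1.49, adjusted p = 6.18e-13, adjusted p = 0.236 with an estimated correlation). Of 25 G2/M genes 24 were higher and 0 lower, the same adjusted over the list alone (median 0.41, adjusted p = 4.74e-08, adjusted p = 0.222 with an estimated correlation). Of 25 genes of G1/S and replication 21 were lower and 1 higher, the same adjusted over the list alone (median -0.51, 0.13 under scaling to mitochondrial mRNAs, adjusted p = 3.1e-06, adjusted p = 0.303 with an estimated correlation). Of 79 ribosomal protein genes 59 were lower and 0 higher, the same adjusted over the list alone (median -0.32, 0.32 under scaling to mitochondrial mRNAs, adjusted p = 1.32e-07, adjusted p = 0.591 with an estimated correlation).

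Other lists called between the depletions were higher with POLR1A depleted in most cases, and none of the calls held with an estimated correlation. Immediate early genes had 20 higher and 3 lower of 30 (median 0.70, adjusted p = 3.3e-05, 0.355 estimated), Pol III factors 15 and 3 of 21 (median 0.53, adjusted p = 0.000268, 0.0703 estimated) and heat shock genes 10 and 4 of 16 (median 0.40, adjusted p = 0.0253, 0.641 estimated), the same adjusted over the list alone. Short-lived mRNAs had 21 higher and 6 lower of 31, 23 and 6 adjusted over the list alone (median 0.55, adjusted p = 0.000105, 0.33 estimated). Genes of chromatin architecture had 20 and 3 of 30, 21 and 3 adjusted over the list alone (median 0.46, adjusted p = 9.74e-06, 0.168 estimated). Genes of the ATF4 response had 15 and 6 of 25, 16 and 6 adjusted over the list alone (median 0.33, adjusted p = 0.0363, 0.461 estimated). Long-lived mRNAs had 3 higher and 21 lower of 30, 3 and 22 adjusted over the list alone (median -0.25, 0.40 under scaling to mitochondrial mRNAs, adjusted p = 0.00293, 0.657 estimated). Blood cell markers had 0 higher and 8 lower of 11 (median -2.13, adjusted p = 0.0294, 0.236 estimated) and mitochondrial mRNAs 0 and 7 of 13 (median -0.45, 0.21 under scaling to themselves, adjusted p = 0.026, 0.704 estimated), the same adjusted over the list alone.

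Actinomycin D and POLR1A depletion differed in histones, p53 targets and genes that were low in the POLR1A line. H2AC7 was at least 2370-fold lower with actinomycin D, or 1460-fold without its replicate 2, and H3C12 was lower at a log2 fold change of -7.65 (SE 0.12), H2BC11 at -7.80 (SE 0.16) and H3C4 at -8.81 (SE 0.51). H4C12 was lower at -7.80 (SE 0.50), and without actinomycin D replicate 2, which held all its counts there, by at least 3300-fold. GALNT3 was higher with actinomycin D by 4.80 (SE 0.21), VSNL1 by 4.31 (SE 0.17), MAL2 by 4.16 (SE 0.06), SYK by 3.93 (SE 0.20) and PPP1R12C by 3.92 (SE 0.11). Of 30 p53 target genes 27 were lower and 1 higher with actinomycin D, the same adjusted over the list alone (median -1.93, adjusted p = 2.86e-15, adjusted p = 0.0282 with an estimated correlation). Of 79 ribosomal protein genes 78 were higher and 0 lower, the same adjusted over the list alone (median 0.94, adjusted p = 1.41e-28, adjusted p = 0.236 with an estimated correlation). Over all genes 5757 were higher and 7502 lower, 43.4% and 72.6% higher under scaling to mitochondrial mRNAs. The median of all genes was -0.115, 0.414 under that scaling and -0.275 with library totals alone.

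Further lists differed between actinomycin D and POLR1A depletion, and their calls were lost with an estimated correlation. Lower with actinomycin D were the immediate early genes, 30 of 30 (median -3.11, adjusted p = 5.21e-15, 0.126 estimated), the histones, 39 of 40 (median -6.06, adjusted p = 6.32e-17, 0.189 estimated) and the NF-kB targets, 8 of 15 with 1 higher (median -0.74, adjusted p = 0.0349, 0.178 estimated). Short-lived mRNAs, with 27 lower and 2 higher of 31 (median -3.06, adjusted p = 3.27e-12, 0.127 estimated), and KRAB zinc finger genes, with 27 and 2 of 31 (median -1.23, adjusted p = 3.77e-07, 0.06 estimated), were lower too. Mitochondrial mRNAs had 8 lower and 1 higher of 13 (median -1.17, adjusted p = 0.00913, 0.646 estimated). Higher were G1/S genes, 24 of 25 (median 0.68, adjusted p = 2.82e-11, 0.175 estimated), and long-lived mRNAs, 28 of 30 with 1 lower (median 0.65, adjusted p = 1.94e-14, 0.236 estimated). Sterol genes had 15 higher and 3 lower of 20 (median 0.56, adjusted p = 0.000111, 0.355 estimated), Pol II subunits 14 and 2 of 18 (median 0.27, adjusted p = 0.00326, 0.418 estimated) and rRNA genes 5 and 0 of 5 (median 1.06, adjusted p = 0.0454, 0.539 estimated). Counts adjusted over the list alone were the same for all of these. Ribosome biogenesis factors had 28 higher and 10 lower of 40, 28 and 11 adjusted over the list alone (median 0.47, adjusted p = 0.000129, 0.511 estimated).

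Actinomycin D and POLR2A depletion, which both act on Pol II transcription, differed in histones and in weakly expressed genes. H2AC7 was at least 629-fold lower with actinomycin D, or 386-fold without its replicate 2. H4C12 was lower at a log2 fold change of -6.45 (SE 0.52), at -5.86 without actinomycin D replicate 3, and by at least 1300-fold without replicate 2, which held all its counts there. H2BC11 was lower at -5.97 (SE 0.19), H3C4 at -5.91 (SE 0.68) and H2AC12 at -5.87 (SE 0.14). PRKAA2 had 670 counts with actinomycin D and 3 with POLR2A depleted, a ratio of 151 with a counting interval from 51.4 to 733, or 278 without POLR2A-depleted replicate 2. CEMIP, a hyaluronan-degrading protein, was higher with actinomycin D by 4.24 (SE 0.12), MEF2C by 4.12 (SE 0.12), ZNF704 by 3.79 (SE 0.08) and SEMA3A by 3.57 (SE 0.09). Of 4118 long non-coding RNAs 2442 were lower and 217 higher with actinomycin D, 2427 and 215 adjusted over the class alone (median -1.39, adjusted p = 4.97e-10, adjusted p = 0.0893 with an estimated correlation). Over all genes 7337 were higher and 9389 lower, 43.9% higher, 74.9% under scaling to mitochondrial mRNAs and 31.9% with library totals alone. The median of all genes was -0.175, 1.024 and -0.418 under these scalings, and 71.2% of calls were higher among genes with an average log2 CPM of 3 or more.

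Of 14958 protein-coding genes 6681 were higher and 5075 lower with actinomycin D than with POLR2A depleted, 6724 and 5109 adjusted over the class alone, with a test pointing up, a median of 0.14, -0.10 with library totals alone, and a mean of -0.47 (adjusted p = 3.64e-09, adjusted p = 0.0363 with an estimated correlation). The lists called here lost their calls with an estimated correlation. Histones had 39 lower of 40 (median -4.73, adjusted p = 5.19e-12, 0.259 estimated), immediate early genes 28 lower and 1 higher of 30 (median -2.34, adjusted p = 2.68e-09, 0.201 estimated) and short-lived mRNAs 26 and 3 of 31 (median -2.23, adjusted p = 6.87e-08, 0.201 estimated). The p53 targets had 24 lower and 5 higher of 30 (median -1.11, 0.09 under scaling to mitochondrial mRNAs, adjusted p = 6.55e-06, 0.116 estimated), KRAB zinc finger genes 20 and 3 of 31 (median -0.76, 0.43 under that scaling, adjusted p = 0.00307, 0.149 estimated) and mitochondrial mRNAs 13 and 0 of 13 (median -1.57, adjusted p = 1.53e-05, 0.439 estimated). Ribosomal proteins had 74 higher of 79 (median 0.61, adjusted p = 3.14e-17, 0.355 estimated), long-lived mRNAs 28 of 30 (median 0.42, adjusted p = 1.22e-09, 0.33 estimated) and ribosome biogenesis factors 30 of 40 with 5 lower (median 0.41, adjusted p = 3.29e-05, 0.464 estimated). G2/M genes had 20 higher and 2 lower of 25 (median 0.47, adjusted p = 2.45e-06, 0.282 estimated), G1/S genes 15 and 4 of 25 (median 0.37, adjusted p = 0.0151, 0.602 estimated) and sterol genes 16 and 2 of 20 (median 0.95, adjusted p = 8.48e-06, 0.279 estimated). Genes of chromatin architecture had 21 higher and 6 lower of 30 (median 0.63, adjusted p = 3.54e-05, 0.189 estimated), Pol II subunits 13 and 2 of 18 (median 0.32, adjusted p = 0.00837, 0.461 estimated) and Pol III factors 14 and 3 of 21 (median 0.44, adjusted p = 0.0184, 0.172 estimated). Counts adjusted over the list alone were the same for these, while NF-kB targets had 11 lower and 0 higher of 15, 12 and 0 adjusted over the list alone (median -1.49, adjusted p = 0.00779, 0.125 estimated).

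The 3 comparisons with controls shared calls. Depletion of POLR1A and of POLR2A shared 2132 higher genes, where independent lists would share 1610, and 2703 lower genes, where they would share 1234. POLR1A depletion and actinomycin D shared 2362 higher and 1955 lower genes, against 1209 and 1248 for independent lists. POLR2A depletion and actinomycin D shared 2264 higher and 3372 lower genes, against 1951 and 1893. Calls in opposite directions numbered 1899, 2377 and 2635, and no expected number was computed for these. The numbers for independent lists take no account of abundance, on which calls depend. Among genes with an average log2 CPM of 3 or more, the depletions shared 1403 higher and 2294 lower genes, against 841 and 1628. POLR1A depletion and actinomycin D shared 2017 and 1492 there, against 1613 and 1140, and POLR2A depletion and actinomycin D 1688 and 2669, against 1082 and 1863. Simulated unchanged groups set against common simulated controls shared at most 0.1 higher and 0.2 lower genes on average. Those groups held no changed genes to call, so these counts cannot show how much sharing controls adds to the overlap of real calls. Covariances of log2 fold changes were 0.654, 0.355 and 0.554, above the simulated 0.221, 0.222 and 0.219 by 0.433, 0.133 and 0.335. Among genes with an average log2 CPM of 3 or more, a limit chosen after the values were seen, they were 0.173, 0.103 and 0.272, above the simulated values by 0.165, 0.095 and 0.264, so POLR2A depletion and actinomycin D had the largest excess there. Correlations across genes were 0.346, 0.289 and 0.227, and sharing controls alone gave 0.520, 0.550 and 0.519. The 3 control libraries cannot be split into parts of at least 2, so part of the excess may come from sharing them.

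Protein-coding genes were also put into 5 equal groups by span. The shortest had a median span of 5.37 kb and the longest of 164 kb. From the shortest to the longest, the median change was 0.06 and -0.22 with POLR2A depleted, -0.04 and 0.13 with POLR1A depleted and 0.00 and 0.08 with actinomycin D. The 0.06 was 0.02 without control replicate 1 and 0.03 without control replicate 3 or POLR2A-depleted replicate 1, and the -0.04 was -0.02 without POLR1A-depleted replicate 1 and -0.01 without control replicate 2. Among genes with an average log2 CPM of 3 or more the values were -0.13 and -0.43, -0.10 and 0.14, and 0.16 and 0.08, so that the order turned with actinomycin D.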

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

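Of the tests below, that of depth, the second grouping by abundance and the gains of silent genes in the other treatments were chosen only after the result was seen, while the others on where silent genes lie were set beforehand.

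The effects of treatments in 5 gene groups differed when the difference itself was tested. The p53 target genes differed between actinomycin D and POLR1A depletion by a median log2 fold change of -1.93, a call that held with an estimated correlation (adjusted p = 0.0282). Cytosolic ribosomal protein genes fell with POLR1A depleted and rose with actinomycin D, a median difference of 0.94, although these calls were lost with an estimated correlation (adjusted p = 0.453, 0.311 and 0.236 for the difference) and their fall with POLR1A depleted became 0.03 under scaling to mitochondrial mRNAs. Protein-coding genes were called down with POLR2A depleted and up with actinomycin D, a median difference of 0.14 that became -0.10 with library totals alone, and only the call for the difference held with an estimated correlation (adjusted p = 0.076, 0.203 and 0.0363). Long non-coding RNAs were called up with POLR2A depleted and down with actinomycin D, a median difference of -1.39, and these calls were lost with an estimated correlation (adjusted p = 0.178, 0.33 and 0.0893). Genes with no class did the same, with a median difference of -1.47, and lost the calls too (adjusted p = 0.203, 0.453 and 0.125). The medians of both groups with actinomycin D turned under scaling to mitochondrial mRNAs, to 0.36 and 0.35.

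Weakly expressed genes rose in the POLR2A-depleted libraries, by a median of 1.6 in the lowest group by abundance and 0.39 with genes passing and ordered by the other treatments, and whether this underlies the differences in long non-coding RNAs was not tested. Long non-coding RNAs also fell with actinomycin D against controls. Lower depth would leave fewer genes with a count, but before any thinning the lowest POLR2A-depleted library, also the shallowest of all, had 1.18 times the genes of the highest control library, 37371 against 31743. Reads spread evenly over the genome, such as those of contaminating DNA, would reach silent genes alike. Silent genes just downstream of an expressed gene on its strand gained more counts per exon kb than those far from any. The ratio was 4.88 (interval 4.31 to 5.52). Far smaller gains under POLR1A depletion and actinomycin D had ratios of 4.38 (interval 3.61 to 5.32) and 3.66 (interval 2.97 to 4.53). Choice by low control counts can give such ratios, so none of these tests an even spread. Genes far from expressed genes still gained, from 0.00454 to 0.0615 CPM per kb, so an even spread stays open. Transcription running past gene ends may contribute, but the gain on the same strand was only 1.27 times that on the other (interval 1.08 to 1.5), between the bounds set for either outcome and limited by an unstated strand setting, so it cannot be told apart from other sources near expressed genes, and true induction after loss of Pol II was not tested.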

How the results depend on the processing

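The restriction to genes with an average log2 CPM of 3 or more was chosen after the counts of calls and the overlaps were seen, and the grouping by abundance in the other treatments and the splits of the libraries were run after the results too.

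Counts of calls stayed within 1.5 times with DESeq2 size factors, with library totals alone, without the filter, in the Wald test of DESeq2, in fits over only the groups compared and on leaving out each library. In the last case higher genes numbered 4364 to 4745 with POLR1A depleted, 7193 to 8241 with POLR2A depleted and 5500 to 5787 with actinomycin D, and lower genes 3772 to 4080, 6422 to 6712 and 6090 to 6649. For POLR1A against POLR2A depletion the ranges were 6391 to 6698 and 7563 to 7767, for actinomycin D against POLR1A depletion 5315 to 5519 and 6924 to 7223, and against POLR2A depletion 7188 to 7287 and 8936 to 9821.

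With an absolute log2 fold change of 1 or more, higher and lower genes numbered 1165 and 1156 (POLR1A), 5181 and 2274 (POLR2A) and 916 and 4008 (actinomycin D). Between the depletions 2195 were higher. For actinomycin D 1713 were higher and 4492 lower than with POLR1A depleted, and 1655 higher than with POLR2A depleted. Shared higher and lower calls became 582 and 404 for the depletions, 208 and 389 for POLR1A and actinomycin D, and 361 and 926 for POLR2A and actinomycin D, all by the construction of that limit.

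Scaling to mitochondrial mRNAs moved lower genes to 1263 with POLR1A depleted, higher genes to 5041 with POLR2A depleted, and higher and lower genes to 11900 and 2061 with actinomycin D. The counts became 11332 and 3929 between the depletions, 9256 and 3495 for actinomycin D against POLR1A depletion and 12914 and 4335 against POLR2A depletion. Directions of tests turned for Pol III factors (adjusted p = 0.836) and ribosome biogenesis factors (0.858) with actinomycin D, and for ribosomal proteins (0.0869) and long-lived mRNAs (0.0187) between the depletions. POLR1A with actinomycin D turned to 0.59, and POLR2A to 0.40 between the depletions and 0.30 between actinomycin D and POLR2A depletion. Called classes rose from 1 to 7 with POLR1A depleted, from 3 to 6 with actinomycin D and from 1 to 5 between these. With library totals alone 2 classes were called with POLR1A depleted and 1 with actinomycin D. The cause was not tested, though mitochondrial mRNAs fell with actinomycin D.

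With the correlation estimated from the data, called lists went from 12, 15 and 13 against controls to 1, 1 and 1, from 14 to 0 between the depletions, and for actinomycin D from 14 to 1 against POLR1A and from 16 to 0 against POLR2A depletion. Called classes went from 1, 4, 3, 4, 1 and 5 in the same order to 0, 0, 0, 0, 0 and 1. The cause was not tested.

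Among genes with an average log2 CPM of 3 or more, of which fewer were tested, 2506 were higher with POLR2A depleted, 3803 lower with actinomycin D and 2421 lower between the depletions. With actinomycin D 4178 were lower than with POLR1A and 2533 than with POLR2A depleted, and the depletions shared 1403 higher genes. With POLR2A depleted, the median change of protein-coding genes in the shortest group by span turned from 0.06 to -0.13 in this restriction, and that in the longest went from -0.22 to -0.43. On leaving out a library they ran from 0.02 to 0.07 and from -0.25 to -0.21. The shortest group went from -0.04 to -0.10 with POLR1A depleted and from 0.00 to 0.16 with actinomycin D in this restriction.

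Replicate numbers did not pair the libraries, as correlations of deviations ran from -0.061 to 0.039 for the same number and from -0.064 to 0.052 for others, and 2 of 12 libraries correlated best with a library of their own number. With the number as a replicate block, higher and lower genes were 4654 and 4180, 7576 and 6518, and 5702 and 6468 against controls. Between treatments they were 6728 and 7518, 5590 and 7231, and 7242 and 9175. The block changed no list call and 1 class call.

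Of 203 fold changes of named genes, 5 turned, AHRR to 0.05 and KRT18 to 0.39 with actinomycin D among these, and 5 lost their call under scaling to mitochondrial mRNAs, and 2 lost it with library totals alone. On leaving out a library 8 values lost their call and 1210 stayed as they were, called or not, and 30 of 203 lay under the limit of 1. Genes filtered out in an alternative had no value there. Each comparison had 10 splits of its 6 libraries, too few for a share under 0.05. The real split gave 9231, 14475, 12601, 14677, 13259 and 16726 calls and the highest other 0, so 1 of 10 splits reached the real count. Small changes can be missed, but with 200 changed genes the simulation cannot give the share recovered at the real number of calls.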

Other observations

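Tests on the POLR1A line and on the p53 list were chosen after their results were seen, except that for loss of chromosome segments.

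Some targets of the aryl hydrocarbon receptor rose with POLR1A depleted, the group treated with indole-3-acetic acid and doxycycline. CYP1A1, a cytochrome P450, rose by 3.27 (SE 0.26), from 0.739 ± 0.17 to 7.29 ± 0.621 CPM, CYP1B1 by 2.73 (SE 0.17) and the receptor's repressor AHRR by 1.15 (SE 0.14) (SD, n = 3 each). CYP1A1 also rose by 1.61 (SE 0.28) with POLR2A depleted and 1.06 (SE 0.28) with actinomycin D, where CYP1B1 had no call and AHRR fell by 0.82 (SE 0.15) and 0.87 (SE 0.15), the latter turning to a rise of 0.05 under scaling to mitochondrial mRNAs. Of 14 tested targets 6 rose and 3 fell, also adjusted over the list alone, without a call for the list (median 0.24, adjusted p = 0.29). The keratin mRNAs KRT18 and KRT8, placed beforehand in the long-lived list, fell by 1.23 (SE 0.07) and 0.86 (SE 0.05) with POLR1A depleted and by 1.33 (SE 0.07) and 0.44 (SE 0.05) with POLR2A depleted, and KRT18 fell by 0.53 (SE 0.07) with actinomycin D, a rise of 0.39 under scaling to mitochondrial mRNAs. The constitutive chaperone HSPA8 fell in all 3 treatments, by 0.85 (SE 0.07) with POLR1A depleted, 1.61 (SE 0.07) with POLR2A depleted, from 3580 ± 469 to 1170 ± 7.57 CPM (SD, n = 3 each), and 1.21 (SE 0.07) with actinomycin D. With actinomycin D the host transcript of the miR-17 cluster, MIR17HG, fell by 3.70 (SE 0.14), against 1.58 (SE 0.12) with POLR1A and 0.74 (SE 0.11) with POLR2A depleted.

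Among RNAs made by Pol III, 10 were tested, with 0, 2 and 4 rising and 1, 1 and 2 falling in the POLR1A, POLR2A and actinomycin D comparisons. Adjusted over the list alone these were 0, 2 and 5 and 0, 1 and 2, with no call for the list (adjusted p = 0.948, 0.991 and 0.336). RN7SL1, the RNA of the signal recognition particle, rose by 0.65 (SE 0.18) with POLR2A depleted and 1.19 (SE 0.18) with actinomycin D. Its call with POLR2A depleted was lost without control replicate 3, at 0.57. Of 10 spliceosomal RNAs made by Pol II, 2, 6 and 1 fell and 0 rose in the same comparisons, with 2, 6 and 0 falls adjusted over the list alone, without a call (adjusted p = 0.092, 0.0623 and 0.954). Of 12 nuclear architectural RNAs 4, 3 and 2 rose and 4, 7 and 6 fell, 4, 3 and 3 and 5, 7 and 6 adjusted over the list alone, without a call (adjusted p = 0.536, 0.339 and 0.326).

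The 20 protein-coding genes that were lowest in the POLR1A line among those with an average log2 CPM of 3 or more, from GALNT3 on, had a median log2 fold change of -2.72 there, -1.54 with POLR2A depleted and 0.28 with actinomycin D. Loss of chromosome segments in the clone would lower neighbours too, but the 200 nearest tested genes had a median of -0.01 (interval -0.16 to 0.10). Stopped transcription over the treatment time would lower these genes under the other treatments. With actinomycin D 17 of the 20 lay above -1, but levels relative to all RNA hide a shared fall, so this decides nothing. Of the 20, 13 fell by 1 or more with POLR2A depleted, which goes with such a stop, so it stays open. They lay 0.58 above their POLR1A-line value with POLR2A depleted (interval -0.71 to 0.87). The other 7, GALNT3, PPP1R12C and MAL2 among these, lay 2.45 above that value in the lower of the other treatments (interval 2.06 to 3.68). The split was made on the POLR2A values after they were seen, so these gaps alone decide nothing. A transgene in PPP1R12C, a common site for inserted expression cassettes, is a candidate explanation for that gene, since the 14 tested genes within 100 kb had a median of 0.41 (range -1.28 to 2.17), but the labels do not say where the receptor gene sits. A clonal difference of the line and an effect of depletion stay open, as the line had no untreated libraries here.

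The p53 list was higher in the POLR2A-depleted libraries as well, at a median of 0.75, although its call was lost with an estimated correlation (adjusted p = 0.0703). Background reads on weakly expressed genes would leave strongly expressed members in place, but the 25 members at 10 CPM or more in controls had a median of 0.73 (interval 0.33 to 1.07), with 19 higher and 2 lower. None of the 3 other scalings accounted for it, as the lowest median over them was 0.46 and the highest 0.87. All the scalings rest on RNA within the libraries, so a change in RNA per cell could not be tested. A p53 response to loss of either polymerase, or a difference between the lines and wild-type cells, may underlie the higher p53 list. These could not be separated without untreated libraries of the lines.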
